A study of Xenopus laevis with 6 samples.

How the data were processed

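RNA of Xenopus laevis PGCs and of stage-matched endoderm cells was sequenced in 6 libraries, 3 per cell type. Per the labels' protocols, cells of stage 12-14 embryos were lysed, ribosomal RNA was depleted, and 3 aliquots of 1 ng of each depleted sample were made into ScriptSeq v2 libraries and read as 100-bp paired ends on an Illumina HiSeq. The labels do not say whether the libraries of a group came from separate cell collections, and were taken as replicates numbered by their titles. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie2 2.2.6, SAMtools 1.2, HTSeq 0.6.0 and edgeR 3.12.0 were used, with no role given, and the settings and genome build are not given in the sources used here beyond the version tags v9.1 and v7.1 of the tables. Whether counting used strand or kept reads that match more than 1 gene is likewise not given in the sources used here, so near-identical copies, overlapping genes and antisense genes are uncertain.

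Each of the 2 deposited tables held whole-number read counts per gene model and library, 10364 gene models in v9.1 and 7902 in v7.1, and in both the smallest total over the 6 libraries was 150, so that the authors had removed sparser genes before deposit. The deposited normalized signal columns were the counts divided by 1 constant per library, equal to the TMM effective library size scaled as for CPM, and were not used for tests. The deposited log2 columns held the authors' fold change of endoderm over PGC and mean abundance, per the file headers. The deposited p-value and FDR columns came from a likelihood ratio test by the authors, per the file headers, and the FDR was the Benjamini-Hochberg adjustment of those p-values over the listed gene models. No column of per-sample values was left out.

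Symbols were those paired with gene models in the tables. The v9.1 table named 6808 symbols, 91.0% of which were in the RefSeq gene table of assembly Xenopus_laevis_v10.1, which was used for names only. No coordinates were analysed here.

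Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM scaling and 1 term for cell type, two-sided, with Benjamini-Hochberg adjustment at 0.05. The filter filterByExpr, with a minimum count of 10 and minimum total of 15, removed no gene model. CPM are counts per M of the TMM effective library size. Standard errors came from the same fit. A fold against a group with 0 counts is a bound against 3 counts over that group, and for genes with 1 to 3 counts in a group the summed counts are given without a fold. Such a bound covers counting error only, and the true fold can lie below it. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over all tested lists, beside camera with an estimated correlation and fry. For symbols with exactly 2 gene models, edgeR's quasi-likelihood test compared the PGC over endoderm ratio of both, with library as a block. That comparison had been planned for L and S homeologs named in the symbols, but v9.1 symbols carry no such suffix for most genes, so gene models were paired by symbol and have no order.

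The comparison, the tests, the 22 lists, the rule for named genes and the first set of other settings were chosen before the data were examined. Named genes were the sox7 gene models, the 10 largest called changes in each direction above a mean of 5 CPM with no overlap between groups, up to 4 called members per list with the largest change, up to 4 opposite pairs with the largest difference, and nanos1, dazl, ddx25, pgat, dnd1, grip2, sox17a, sox17b, gata4 and gata6. Of the genes this rule gave, 98 v9.1 gene models passed the test, and values are given for a part of them. sox17b was not analysed here, nor was pgat in v9.1. The lists were germ plasm and germ line RNAs, piRNA pathway, oocyte and maternal-effect genes, vegetally localized maternal mRNAs, endoderm regulators, mesoderm markers, ectoderm and neural markers, pluripotency-associated genes, the Sox family, chromatin and DNA methylation regulators, RNA polymerase II elongation, nuclear-encoded oxidative phosphorylation, mitochondrial genome transcripts, mitochondrial biogenesis, cytosolic ribosomal proteins, cell cycle, apoptosis, adhesion and migration, Wnt signalling, TGF-beta and BMP signalling, dissociation and stress response, and small GTPases and cytoskeletal motors. A list with at least 5 gene models was tested.

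That first set was DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, other low-count filters, a replicate block, leaving out each library, other fold thresholds, and for lists and pairs the v7.1 table, summed gene models and a higher count minimum. Total-count scaling, lowess offsets (library scaling that follows expression level), thinning every library to 9.94 M counts and counts divided by their index of dispersion were added after seeing the data.

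The steps were tested on simulated counts drawn from the means and library sizes of these libraries. In v9.1, of 50 genes changed by each size, 4% were recovered at 1.5-fold, 24% at 2-fold, 60% at 4-fold and 74% at 8-fold, with 2 false calls, and in v7.1 4%, 22%, 56% and 68%, with 3 false calls. The list test found the 1 raised list and none of 20 unchanged ones. Genes were simulated independently of each other, so that result does not cover lists whose members vary together. In the data the estimated correlation reached 0.0935, for the oocyte list. The pair test recovered 4% of 2-fold and 29% of 4-fold differences with 1 false call. The simulation changed only 50 genes per size, far fewer than were called in the data, so its Benjamini-Hochberg cutoff was stricter. Its recovered shares and false calls, those of the pair test included, therefore do not carry over to the data. A change that was not called may still be one that this depth and spread could not show.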

Results

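Ribosomal-RNA-depleted RNA of primordial germ cells (PGCs) and of endoderm cells from stage 12-14 Xenopus laevis embryos was sequenced in 6 libraries, 3 of PGCs and 3 of endoderm. PGCs are the embryonic precursors of eggs and sperm. In Xenopus they inherit germ plasm, an RNA- and mitochondria-rich part of the vegetal egg cytoplasm, and at these stages they lie among endoderm cells. Read counts were given for 10364 gene models in a table named v9.1 and for 7902 in a table named v7.1. Total counts in the v9.1 table were 28.3, 20.2 and 9.9 M in endoderm replicates 1, 2 and 3, and 16.9, 14.8 and 14.5 M in PGC replicates 1, 2 and 3. Levels are given in CPM, scaled for library size and composition, as mean ± SD over n = 3 libraries per group, and fold changes as log2 of PGC over endoderm ± standard error. The 10 most counted genes of each library took 18.0 ± 0.115% of its counts in PGCs and 9.42 ± 0.367% in endoderm (SD, n = 3). Counts spread between libraries of a group far beyond sampling noise, with a chi-square per degree of freedom of 40.4 to 68.0 between pairs of endoderm libraries and 55.1 to 59.2 between pairs of PGC libraries. Each library was counted as 1 sample, although reads copied within a library would give such values between aliquots of 1 sample as well.

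The series asks which RNAs PGCs carry in excess over neighbouring endoderm once the lineages have parted, and its title names sox7, a SoxF transcription factor. The germ line genes used to check the labels were far higher in PGC libraries. ddx25 (Xelaev18035291m), which encodes the germ plasm DEAD-box helicase known in Xenopus as DEADSouth, stood at 71752 ± 1534 CPM in PGCs and 385 ± 11.6 CPM in endoderm, a log2 fold change of 7.54 ± 0.04. dazl (Xelaev18031029m), an RNA-binding translational activator of germ cells, stood at 16463 ± 19.5 against 81.6 ± 7.14 CPM (7.66 ± 0.07), and nanos1 (Xelaev18034293m), a translational repressor, at 6457 ± 292 against 29.9 ± 6.08 CPM (7.75 ± 0.15). grip2, whose RNA is a germ plasm component, stood at 38292 ± 705 against 129.6 ± 9.16 CPM in one gene model (Xelaev18023956m, 8.21 ± 0.06) and rose by 8.27 ± 0.28 in the other (Xelaev18025874m). dnd1 (Xelaev18017004m), which encodes a germ cell RNA-binding protein, rose by 5.77 ± 0.28, from 19.4 ± 7.94 to 1051 ± 43.9 CPM. Over 15 alternative settings the log2 fold change was 7.53 to 9.26 for ddx25, 7.62 to 8.82 for dazl and 7.66 to 8.55 for nanos1. It was 8.18 to 9.61 for grip2 Xelaev18023956m and 5.48 to 6.15 for dnd1.

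sox7 had 2 gene models. Xelaev18028242m stood at 269 ± 43.0 CPM in PGCs and 3.63 ± 3.11 CPM in endoderm, a 68.7-fold rise with a standard error of 0.53 on the log2 scale and an adjusted p of 3.1e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Xelaev18030202m stood at 0.92 ± 1.59 CPM in PGCs and 3.60 ± 3.04 CPM in endoderm, with a log2 fold change of -1.96 ± 2.24 and an adjusted p of 0.571 by the same edgeR test, so no difference was detectable for it at this depth. Its PGC counts were 52, 0 and 0. Without PGC replicate 1 the PGC group was at 0, with an edgeR adjusted p of 0.114 (0.0985 to 0.738 over 13 alternatives). The floor there was 48.2-fold lower, but it covers counting error only and leaves out the library with all PGC counts. That floor therefore shows no fall in PGCs. The fitted value of this gene model was -7.12 when library scaling followed expression level. By the same test the adjusted p was 9e-19 for ddx25, 1.5e-15 for dazl, 2.2e-12 for nanos1, 6.5e-17 for the more abundant grip2 gene model and 1.6e-08 for dnd1, and each of these was higher in every PGC library than in every endoderm library.

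**Figure D1:**
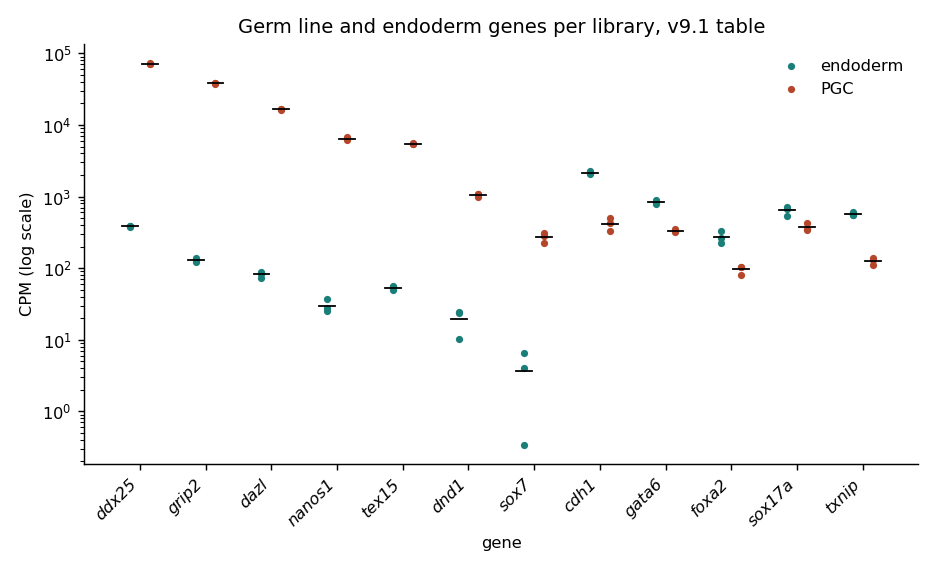
CPM (log scale) of 12 genes in each of the 6 libraries, with endoderm points to the left and PGC points to the right of each gene, and bars at the group means. The genes were picked by hand, and each is drawn by its gene model with the smallest adjusted p. The second sox7 gene model, which was not called, and gata4, which was higher in PGCs, are not drawn. ddx25, grip2, dazl, nanos1, tex15, dnd1 and sox7 lie higher in PGC libraries, and cdh1, gata6, foxa2, sox17a and txnip lower. The direction of sox17a turned when library scaling followed expression level.

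Of the endoderm regulators used to check the labels, gata6 fell in PGCs by 1.33 ± 0.10 on the log2 scale (Xelaev18033648m, 333 ± 14.4 against 836 ± 51.2 CPM; -0.45 when library scaling followed expression level), and its other gene model fell by 0.74 ± 0.18 (Xelaev18031904m), a call that was lost under total-count scaling (-0.42) and when library scaling followed expression level (-0.27). The sox17a gene models fell by 0.77 ± 0.13 (Xelaev18033724m) and 0.48 ± 0.14 (Xelaev18032020m), and turned to 0.072 and 0.29 when library scaling followed expression level, while total-count scaling gave -0.46 and -0.16. The smaller change of sox17a missed the threshold under total-count scaling, with counts divided by their index of dispersion (-0.27) and without PGC replicate 2 or 3 or endoderm replicate 1 or 3, at log2 fold changes of -0.42, -0.50, -0.35 and -0.38. gata4, a zinc-finger regulator of endoderm and heart, did not fall. Xelaev18030192m was higher in PGCs by 1.53 ± 0.15 (308 ± 26.8 against 107 ± 10.4 CPM), and Xelaev18028230m by 0.36 ± 0.12, with 0.68 under total-count scaling, 1.12 when scaling followed expression level and 0.58 with divided counts. That call was lost without PGC replicate 2 or 3 or endoderm replicate 1 or 2, at 0.37, 0.27, 0.41 and 0.34.

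Across the v9.1 table, 3040 of 10364 gene models (29.3%) differed between PGCs and endoderm by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 1301 were higher and 1739 lower in PGCs. At an unadjusted p under 0.05 there were 4012. With libraries scaled by total counts alone the split turned, to 1932 higher and 1117 lower, as it did when library scaling followed expression level, to 1279 and 1196. Total-count scaling moved the median log2 fold change of all gene models from 0.07 to 0.39, and scaling by expression level to -0.06. The median also varied with level in the main scaling, from 0.61 in the tenth of gene models with the lowest mean CPM to -0.75 in the tenth with the highest. The 3 libraries of one group lay wholly above those of the other for 4997 gene models (48.2%, where chance gives 10%). The labels' protocols describe library aliquots of each RNA sample, so p-values measure only the spread between these libraries, which may be technical.

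**Figure D2:**
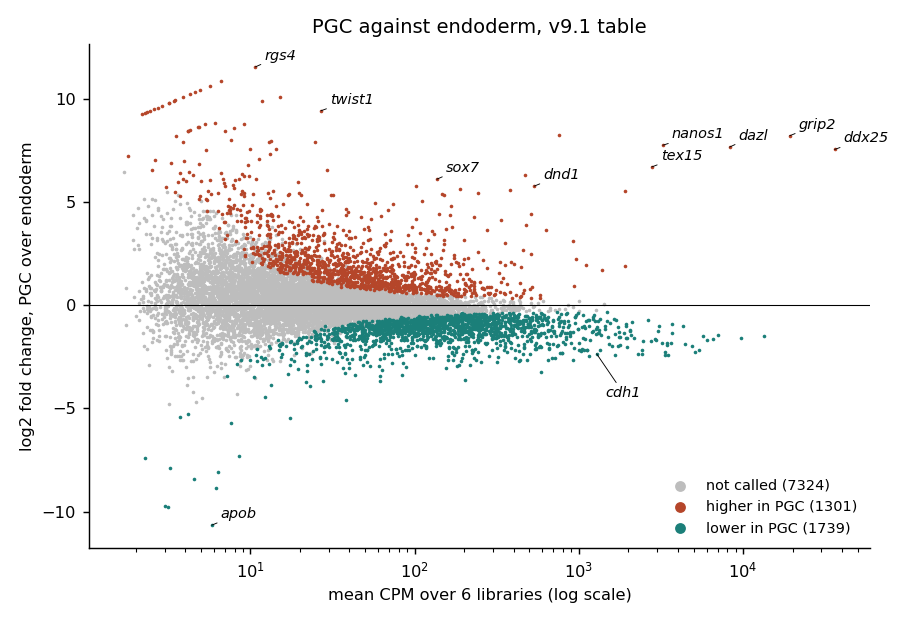
Log2 fold change of PGC over endoderm against the mean CPM over 6 libraries (log scale) for the 10364 gene models of the v9.1 table, coloured by the edgeR call. The 1301 gene models called higher include abundant germ line RNAs and sparse ones at the upper left, and the 1739 called lower lie mostly at high mean CPM, a split that turned to 1932 and 1117 with libraries scaled by total counts alone and to 1279 and 1196 when library scaling followed expression level.

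At a fitted change of at least 2-fold, 2102 called gene models remained, 1058 higher and 1044 lower in PGCs, and with total-count scaling 1604 were higher and 576 lower. The test was against no change, and glmTreat, which tests against 2-fold itself, called fewer, as given below. The largest rises among gene models above a mean of 5 CPM were in genes close to silence in endoderm. rgs4, which encodes a regulator of G-protein signalling, had 0 counts over the endoderm libraries and 21.4 ± 11.9 CPM in PGCs, at least 385-fold higher against 3 counts over the group. vgll3 was at least 227-fold and cdkn2c, which encodes a cyclin-dependent kinase inhibitor, at least 197-fold higher by the same floor. These bounds follow endoderm depth, and without endoderm replicates 1 and 2 they were 204- and 256-fold for rgs4, 120- and 151-fold for vgll3 and 104- and 131-fold for cdkn2c. clic4 had 1 count over the endoderm libraries and 1545 over the PGC libraries, and pcdh8, a protocadherin of paraxial mesoderm, 1 and 1240. Likewise tbx4 had 1 and 621, shox2 1 and 533, the Spemann organizer gene gsc 2 and 943 and pax5 2 and 839. The tbx4 call was lost, at a fitted 5.78, when library scaling followed expression level. twist1, a regulator of mesoderm, rose by 9.42 ± 0.77 from 4 counts over the endoderm libraries to 2784 over the PGC libraries. Its lowest value over 15 alternatives was 7.60. Endoderm replicate 1 held all endoderm counts of pcdh8, shox2, gsc, pax5 and twist1, and without it twist1 was at least 501-fold higher. Floors, here and below, cover counting error only, and reads copied from the same molecule are not independent. Counts spread more widely, with a median variance over mean of 40.7 in endoderm and 41.5 in PGCs at mean counts of 50 to 6400. In endoderm replicate 2, 303 gene models had 0 counts although the other endoderm libraries averaged at least 50. The true fold can therefore lie well below a floor. A floor without the library that held a group's counts covers only the libraries left, and can exceed the fold over all libraries.

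The largest falls were in sparse genes as well. apob, which encodes the apolipoprotein of lipid-carrying particles, had 0 counts over the PGC libraries and 11.6 ± 2.48 CPM in endoderm. Against 3 counts over the group apob was 186-fold lower, a floor for counting error only (118-fold without PGC replicate 1). asap3 had 1 count over the PGC libraries and 661 over the endoderm libraries, and slurp1l 2 and 589. The citrate transporter gene slc13a5 fell by 7.30 ± 1.55. PGC replicate 3 held its PGC counts. Without that replicate slc13a5 was at least 208-fold lower, a floor over the other PGC libraries only. gab3 fell by 5.44 ± 1.04, prokr2 by 4.58 ± 0.92 and pls1, which encodes a fimbrin, by 3.91 ± 0.80. Without PGC replicate 1 gab3 stood at -7.25 and prokr2 at -3.98, and pls1 at -4.67 without PGC replicate 3 and -2.88 without endoderm replicate 2. dnajc18 fell by 4.47 ± 1.25 and the matrix metalloproteinase gene mmp2 by 3.87 ± 1.16. The dnajc18 call was lost without PGC replicate 3 or endoderm replicate 1 or 3 (-4.04, -4.42 and -4.21), and its value was -7.18 without PGC replicate 1. The mmp2 call was lost without PGC replicate 3 or endoderm replicate 1 or 2 (-3.68, -3.98 and -2.83), and its value was -5.26 without PGC replicate 1.

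Germ line and maternal gene groups rose in PGCs as groups. Of 35 gene models of germ plasm and germ line RNAs, 15 rose, 7 fell and 13 did not pass (15 and 8 adjusted over the list alone), with a median log2 fold change of 0.56. With library scaling by expression level 16 rose and 4 fell. spire1, an actin nucleator, rose by 6.29 ± 0.32 to 930 ± 73.2 CPM, whereas gene models of kif5b, igf2bp3 and dazap1 and that of the germ line helicase ddx4 fell, a set named after its values were seen. Of 21 vegetally localized maternal RNAs, 14 rose and 2 fell (15 and 4 adjusted over the list alone), with a median of 3.65, and both that fell were zfp36l2, a name also given after its values were seen. Of 27 gene models of oocyte and maternal-effect genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.97. Among them cpeb1 (Xelaev18020738m), a regulator of polyadenylation of maternal mRNAs, rose by 5.64 ± 0.37 and patl2, a regulator of oocyte translation, by 5.36 ± 0.77.

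Of 17 gene models of the piRNA pathway, which silences transposons in the germ line, 4 rose and 1, ddx4, fell (4 and 1 adjusted over the list alone), and with scaling by expression level 3 rose and 0 fell. tex15 rose by 6.69 ± 0.08 (Xelaev18006177m) to 5499 ± 97.3 CPM and by 2.01 ± 0.37 (Xelaev18009710m), and mov10l1, a helicase of piRNA biogenesis, by 4.33 ± 0.56 (5.54 without endoderm replicate 2). The fourth, tdrd12 (1.36 ± 0.46), passed only with all 6 libraries or without PGC replicate 1 among the fits that left out 1 library each, with values of 1.09, 1.29, 1.64, 1.46 and 1.12 without PGC replicates 2 and 3 and endoderm replicates 1, 2 and 3. It was also lost, at 1.09, when scaling followed expression level. Of 38 gene models of small GTPases and cytoskeletal motors, 12 rose and 5 fell (13 and 5 adjusted over the list alone). The kinesin gene kif13b rose by 3.13 ± 0.11 (Xelaev18028249m) to 1648 ± 99.7 CPM and by 3.29 ± 0.45 (Xelaev18030206m; 3.87 without endoderm replicate 1), and the 5 that fell were of kif5b, dync1h1 and myo10, named after their values were seen. By limma's camera test with a preset correlation and Benjamini-Hochberg adjustment over 21 lists, adjusted p was 9.23e-22 for germ plasm, 4.5e-53 for vegetal RNAs, 1.57e-11 for oocyte genes, 0.00114 for the piRNA pathway and 2.29e-06 for GTPases and motors. All but the piRNA list held with an estimated correlation, with adjusted p = 0.00693, 0.00252, 0.0495 and 0.0227, and for the piRNA pathway adjusted p = 0.119 with an estimated correlation. The germ plasm list shares 8 gene models with the vegetal list, 6 with the piRNA list and 5 with the motor list.

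**Figure D3:**
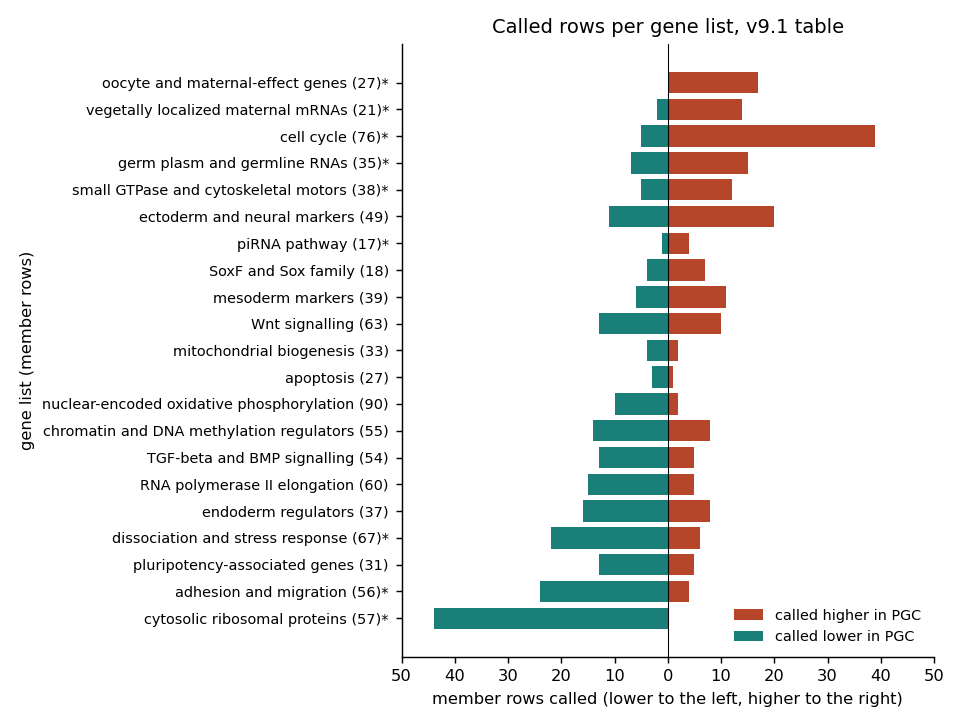
Number of gene models called lower (bars to the left) and higher (bars to the right) in PGCs for each of 21 gene lists, with the number of gene models per list in parentheses and an asterisk where camera with a preset correlation passed. Oocyte genes had 17 higher and 0 lower and ribosomal proteins 0 higher and 44 lower, and the adhesion and stress lists turned direction in camera when library scaling followed expression level.

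Cell cycle genes rose and ribosomal protein genes fell in PGCs. Of 76 cell cycle gene models, 39 rose and 5 fell (41 and 6 adjusted over the list alone), with a median of 0.69. e2f1, a transcription factor of S-phase entry, rose by 5.35 ± 0.23 to 293 ± 54.3 CPM, the cyclin A1 gene ccna1, of meiotic and early embryonic cells, by 5.33 ± 0.76 and 3.24 ± 0.77 (4.56 for the latter without endoderm replicate 3), and the checkpoint kinase gene chek1 by 3.01 ± 0.26. The 5 that fell were gene models of cdknx, ccnd1, mcm6, cdc25b and e2f4, named after their values were seen. Of 57 cytosolic ribosomal protein gene models, 0 rose and 44 fell (0 and 49 adjusted over the list alone), with a mean of -1.11. With total-count scaling 0 rose and 32 fell, and rps4x fell by 1.67 ± 0.27 and rpl14 by 1.65 ± 0.24 in the main scaling. These genes took 0.709 ± 0.0181% of counts in endoderm libraries and 0.414 ± 0.0242% in PGC libraries (SD, n = 3). Camera with a preset correlation gave an adjusted p of 5.67e-09 for the cell cycle and 4.14e-11 for ribosomal proteins, and with an estimated correlation 0.00921 and 0.0495.

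Endoderm regulators split. Of 37 gene models 8 rose and 16 fell in PGCs (9 and 16 adjusted over the list alone), with 10 and 13 under total-count scaling and 10 and 6 when scaling followed expression level. Both gata6 gene models fell as given above, whereas gsc, the mesendoderm gene lhx1 (3.62 ± 0.37, 97.7 ± 11.9 against 7.93 ± 3.88 CPM) and the endoderm homeobox gene mixer (3.15 ± 0.37, 127 ± 19.7 against 14.5 ± 8.22 CPM) rose. Camera pointed to lower with an adjusted p of 0.298, while the median of 0.36 and mean of 0.64 lay above 0, and fry, which asks whether members move 1 way on balance, gave lower at an adjusted p of 0.00128.

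Markers of other germ layers went both ways. Of 39 mesoderm gene models 11 rose and 6 fell (11 and 6 adjusted over the list alone; 6 and 2 when scaling followed expression level). The mesoderm gene models that rose were 7, 7 and 4 without PGC replicates 1, 2 and 3. Among the members were pcdh8 and twist1 above and, downwards, the ventral signal bmp4 by 2.42 ± 0.28. Of 49 ectoderm and neural gene models 20 rose and 11 fell (23 and 11 adjusted over the list alone; 18 and 4 when scaling followed expression level). Those that rose were 12 and 13 without PGC replicates 1 and 3. zic1, a neural zinc-finger gene, rose by 7.89 ± 0.91 to 49.0 ± 4.30 CPM, with 6.64 as its lowest value over 15 alternatives. Endoderm replicate 1 held its endoderm counts. Without that replicate zic1 was at least 453-fold higher, a floor over the other endoderm libraries only. sox2 had 1 count over the endoderm libraries, in replicate 1, and 503 over the PGC libraries. Camera gave an adjusted p of 0.123 for mesoderm and 0.469 for ectoderm and neural genes, and the latter passed as higher, at 0.00413, when library scaling followed expression level (0.00413 to 0.928 over 18 alternatives). By fry, which does not compare a list with other genes, both lists moved higher, at adjusted p of 0.0127 and 0.0313.

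Of 31 pluripotency-associated gene models 5 rose and 13 fell in PGCs (6 and 13 adjusted over the list alone), and 3 rose without each of the 3 PGC replicates. In v7.1 the split turned, to 12 that rose and 10 that fell, and camera pointed to higher. prdm14, a germ cell regulator in mouse, rose by 6.05 ± 1.48, with 4.46 as its lowest value over 14 alternatives. Endoderm replicate 1 held its endoderm counts. Without that replicate prdm14 was at least 147-fold higher, a floor over the other endoderm libraries only. sox3 (sox3.S) rose by 3.59 ± 0.47 (4.4 without endoderm replicate 1). The others that rose were sox2, the second sox3 gene model and klf4. On 0 endoderm counts klf4 was 85.5-fold higher by a floor that covers counting error only (45.4- and 56.9-fold without endoderm replicates 1 and 2). Its call was lost without PGC replicates 1, 2 and 3, at bounds of 87.2-, 80.7- and 88.8-fold and edgeR adjusted p of 0.0615, 0.0681 and 0.0586, and when scaling followed expression level (5.75e-05 to 0.110 over its alternatives). The second sox3 gene model (sox3.L, 3.26 ± 1.09) lost its call without PGC replicates 1, 2 and 3 and endoderm replicate 1, at 3.47, 3.26, 2.99 and 2.89, and when scaling followed expression level (2.66), and its value was 5.7 without endoderm replicate 3. Camera gave lower at an adjusted p of 0.15, with the median at 0.08 and the mean at 1.01, and fry lower at an adjusted p of 0.00263. In v7.1 fry pointed to higher, at an adjusted p of 0.608. Of 18 Sox family gene models 7 rose and 4 fell (7 and 4 adjusted over the list alone; 7 and 2 under total-count scaling), and 3 and 4 rose without PGC replicates 1 and 3. Camera gave an adjusted p of 0.469 and fry an adjusted p of 0.0175 for higher. The 4 that fell were sox17a in both gene models, whose direction turned when scaling followed expression level, and sox5 and sox13, named after their values were seen.

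Adhesion and stress genes fell as groups in PGCs, and the direction of both lists turned when library scaling followed expression level. With an estimated correlation neither held, at camera adjusted p = 0.0927 for adhesion and adjusted p = 0.119 for stress. In the v7.1 table adhesion held, at adjusted p = 0.0153 with an estimated correlation. Of 56 adhesion and migration gene models 4 rose and 24 fell (5 and 27 adjusted over the list alone), with 6 and 18 under total-count scaling and 9 and 12 when scaling followed expression level. cdh1, the epithelial cadherin gene, fell by 2.36 ± 0.13 from 2146 ± 91.6 to 419 ± 83.4 CPM (-1.26 when scaling followed expression level), and ezr, which encodes the membrane-to-actin linker ezrin, by 2.82 ± 0.39. The 4 that rose were kif13b in both gene models, cldn4 and cldn5, the claudins named after their values were seen. Of 67 dissociation and stress gene models 6 rose and 22 fell (6 and 23 adjusted over the list alone), with 11 and 16 under total-count scaling and 14 and 8 when scaling followed expression level. txnip, an inhibitor of thioredoxin, fell by 2.19 ± 0.13 from 572 ± 28.9 to 125 ± 14.3 CPM (-2.26 to -1.56 over 15 alternatives). By contrast hspa5, the endoplasmic reticulum chaperone, rose by 1.84 ± 0.15 from 193 ± 42.6 to 690 ± 23.5 CPM (1.77 to 2.58 over 15 alternatives). Camera gave an adjusted p of 0.00142 for adhesion and 0.0200 for stress, and 0.903 and 0.886 with the direction turned to higher when scaling followed expression level (1.63e-05 to 0.903 and 0.00338 to 0.886 over 18 alternatives). The stress list also missed the threshold under total-count scaling, with counts divided by their index of dispersion and with the gene models of a symbol summed.

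The other lists did not pass camera. By contrast, fry gave lower at adjusted p of 0.0222 for RNA polymerase II elongation, 0.0383 for apoptosis and 0.00128 for TGF-beta and BMP signalling. In v7.1 fry gave adjusted p of 0.599 for elongation, 0.536 for apoptosis, there towards higher, and 0.00261 for TGF-beta and BMP signalling. Oxidative phosphorylation, at a fry adjusted p of 0.108 in v9.1, was lower at 0.00810 in v7.1. fry was run in the main scaling only, and its direction depends on that scaling. Of 55 chromatin and DNA methylation gene models 8 rose and 14 fell (9 and 14 adjusted over the list alone; 14 and 8 under total-count scaling, 12 and 5 when scaling followed expression level). hells, a chromatin remodeller of DNA methylation, rose by 3.60 ± 0.23, smarca5 by 2.06 ± 0.22 and dnmt1, the maintenance methyltransferase, by 1.86 ± 0.22, while the methylcytosine dioxygenase gene tet3 fell by 2.05 ± 0.21. The camera direction was higher at an adjusted p of 0.914, the mean 0.18 and the median -0.04. Of 60 RNA polymerase II elongation gene models 5 rose and 15 fell (5 and 15 adjusted over the list alone; 12 and 6 under total-count scaling, 10 and 5 when scaling followed expression level), with a camera adjusted p of 0.411. The number that rose was 2 without PGC replicate 1 and 3 without endoderm replicate 1 or 3. tbp, the TATA-binding protein gene, rose by 2.05 ± 0.33, and ell2, which encodes an elongation factor, fell by 1.38 ± 0.13 (Xelaev18008057m; -0.65 when scaling followed expression level).

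Of 90 nuclear-encoded oxidative phosphorylation gene models 2 rose and 10 fell (2 and 6 adjusted over the list alone; 3 and 3 under total-count scaling), with a camera adjusted p of 0.799. Those that fell were 6 and 5 without PGC replicates 1 and 2 and 5 without endoderm replicate 1 or 3, and 4 rose without endoderm replicate 1. atp5a1, the ATP synthase alpha subunit gene, rose by 2.69 ± 0.13 from 122 ± 6.42 to 789 ± 106 CPM. With 0 PGC counts, ndufb2 was 112-fold lower by a floor for counting error only (71.2-fold without PGC replicate 1). Of 33 mitochondrial biogenesis gene models 2 rose and 4 fell (2 and 4 adjusted over the list alone; 9 and 3 under total-count scaling, 5 and 3 when scaling followed expression level). Camera with all libraries gave an adjusted p of 0.799, and 4 gene models rose without endoderm replicate 1. polg, the mitochondrial DNA polymerase gene, rose by 2.30 ± 0.55 (3.05 without endoderm replicate 3) and ppargc1a, a co-activator of mitochondrial biogenesis, fell by 2.44 ± 0.17. No gene model matched the list of mitochondrial genome transcripts. Of 27 apoptosis gene models 1, diablo, rose by 1.70 ± 0.39 and 3 fell (1 and 2 adjusted over the list alone; 4 and 2 under total-count scaling, 3 and 1 when scaling followed expression level). The count of risers was 2 without PGC replicate 2 or endoderm replicate 2. The 3 that fell were mcl1, from 636 ± 68.4 to 290.3 ± 12.6 CPM, a call lost when scaling followed expression level (-0.33), birc2 by 0.73 ± 0.10, which was -0.41 under total-count scaling and turned to 0.25 when scaling followed expression level, and casp10 by 1.11 ± 0.38. The casp10 call was lost in every fit without 1 library except that without PGC replicate 3 (-1.32), at -1.26 and -0.81 without PGC replicates 1 and 2 and -1.11, -1.02 and -1.09 without endoderm replicates 1, 2 and 3, and with DESeq2 size factors (-1.06) and total-count scaling (-0.79). Camera gave lower at an adjusted p of 0.799, with the median at -0.07 and the mean at 0.01.

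Of 63 Wnt signalling gene models 10 rose and 13 fell (12 and 14 adjusted over the list alone; 14 and 8 under total-count scaling, 10 and 8 when scaling followed expression level). Camera with all libraries gave an adjusted p of 0.799, and 5 and 6 gene models rose without PGC replicates 1 and 2. sp5, a Wnt target gene, rose by 3.42 ± 0.62 (4.07 without endoderm replicate 1). Of 54 TGF-beta and BMP signalling gene models 5 rose and 13 fell (7 and 14 adjusted over the list alone; 9 and 11 under total-count scaling, 7 and 11 when scaling followed expression level). The number that rose was 3 without PGC replicate 2 and 9 without endoderm replicate 2, and bmp4 fell as above. fst, the follistatin gene, was 152-fold higher on 0 endoderm counts by a floor for counting error only (80.5- and 100.9-fold without endoderm replicates 1 and 2). Camera gave lower at an adjusted p of 0.134, with the median at -0.26 and the mean at 0.09. In all, 9 of the 21 lists with members passed with the preset correlation, 6 higher and 3 lower, and 6 held with an estimated correlation. Only the pluripotency, oxidative phosphorylation and TGF-beta and BMP lists held a gene model with a group at 0, 1 each. Setting that gene model to its bound left the medians as given, which so small a change could hardly have moved.

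The same libraries were also counted on the v7.1 table, which asks whether calls depend on the gene models used. pgat, a germ plasm RNA of Xenopus, was tested there only and stood at 89775 ± 986 CPM in PGCs and 564 ± 13.0 CPM in endoderm, a log2 fold change of 7.31 ± 0.03. trim36, a vegetally localized ubiquitin ligase RNA, rose by 5.50 ± 0.15 and sox7 by 6.15 ± 0.52 (304 ± 45.8 against 3.97 ± 3.40 CPM). The gata6 gene models fell by 0.95 ± 0.14 and 1.19 ± 0.27, while another was not called (-0.82 ± 0.30, edgeR adjusted p 0.0566), nor were those of gata4 (0.76 ± 0.30 and 0.38 ± 0.23, adjusted p 0.0742 and 0.273). By the same edgeR test 2281 of 7902 gene models differed, 1011 higher and 1270 lower in PGCs, and 1615 of them by at least 2-fold (842 higher, 773 lower). With total-count scaling the splits were 1260 to 969 and 1043 to 556, and when scaling followed expression level the first was 1063 to 924. Of 4081 symbols tested in both tables, 1122 were called in the same direction in both, 522 higher and 600 lower, a split that turned to 697 and 410 under total-count scaling and to 553 and 409 when scaling followed expression level. Opposite directions were called for 9, for 21 with DESeq2, for 3, 4 and 7 without PGC replicates 1, 2 and 3, and for 4, 5 and 5 without endoderm replicates 1, 2 and 3. Independent lists of these sizes would share 100.6 higher and 139 lower, but the tables hold the same libraries and are not independent evidence. A further 444 symbols were called in v9.1 alone, 76 in v7.1 alone and 41 had gene models in both directions. In v7.1, 8 lists passed and 6 held with an estimated correlation, where adjusted p = 0.0713 for oocyte genes and adjusted p = 0.0570 for stress, and the piRNA pathway did not, at an adjusted p of 0.608 by camera (3.31e-07 to 0.608 over 18 alternatives).

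The authors' deposited table for v9.1 listed 3417 gene models at a false discovery rate under 0.05, 1564 higher and 1853 lower in PGCs, and 3032 of these were among the 3040 called here. For v7.1 the authors' deposited table listed 2525, of which 2267 were among the 2281 called here. Both sets of calls rest on the same counts and library scaling, so this overlap was largely set in advance and is not independent evidence.

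X. laevis is allotetraploid, and many genes have 2 gene models under 1 symbol, so it was asked whether both changed alike. Of 3512 symbols with exactly 2 gene models in the v9.1 table, 597 had both called, 196 both higher and 353 both lower in PGCs, a split that turned to 334 and 192 under total-count scaling. Both were higher in 127 and 122 symbols without PGC replicates 1 and 2, and opposite in 31, 29 and 31 without PGC replicates 1, 2 and 3. The remaining 48 of the 597 were called in opposite directions, so that 92.0% moved the same way, where 53.4% would be given by chance from the calls of each. slc12a3, a sodium chloride cotransporter gene, rose in Xelaev18010315m by 2.22 ± 0.11 (341 ± 28.9 to 1585 ± 181 CPM) and fell in Xelaev18022526m by 2.66 ± 0.17 (406 ± 32.6 to 64.2 ± 13.4 CPM). The eye and forebrain homeobox gene six3 fell by 2.23 ± 0.26 (Xelaev18026150m) and rose by 5.41 ± 1.07 (Xelaev18028747m). The nuclear receptor gene esrra fell by 2.25 ± 0.43 (Xelaev18022203m; -2.86 without PGC replicate 3) and rose by 2.16 ± 0.51 (Xelaev18024233m; 2.91 without endoderm replicate 3). The kinase gene vrk1 rose by 4.56 ± 1.33 (Xelaev18039592m) and fell by 1.16 ± 0.31 (Xelaev18041273m). The test of the difference itself, edgeR's quasi-likelihood test of gene model by cell type with Benjamini-Hochberg adjustment, gave an adjusted p of 7.66e-06 for slc12a3, 0.00526 for six3, 0.00677 for esrra and 0.0270 for vrk1.

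That test called 342 symbols (9.74%; 878 at an unadjusted p under 0.05), all 48 opposite ones among them, and 168 without PGC replicate 1 and 183 without PGC replicate 2. DESeq2's Wald test of the same difference called 645, and edgeR with counts divided by their index of dispersion called 544 of 1751 tested. In 1148 symbols only 1 of the 2 gene models was called, which by itself shows no difference between them, and the test of the difference called 214 of these. Across symbols, which are not independent replicates, the log2 fold changes of the 2 gene models correlated with Pearson's r of 0.48 and Spearman's rho of 0.46, while the highest r of 1000 shufflings was 0.0583. Whether the gene models of a symbol are the L and S homeologs or parts of 1 gene is not given in the sources used here, and reads that match both copies may have been split or dropped in counting.

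**Figure D4:**
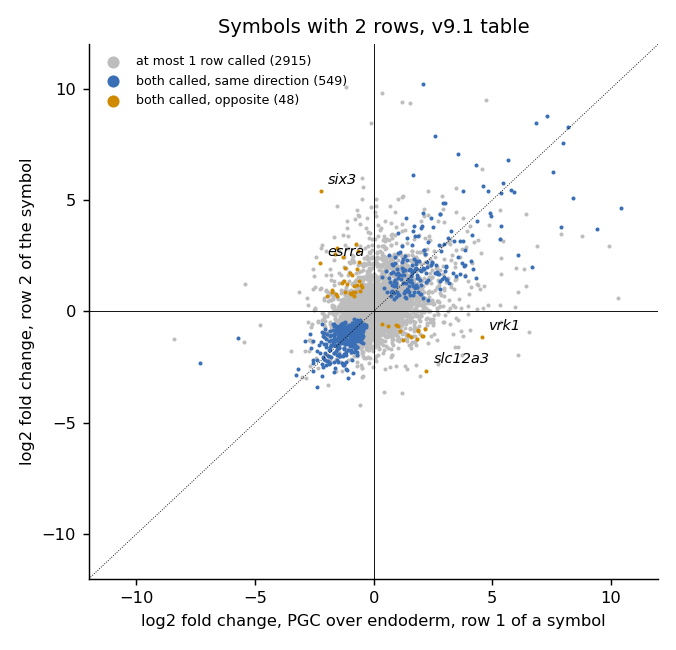
Log2 fold change of PGC over endoderm of the 2 gene models of each of 3512 symbols, with the dotted line where both are equal. Of the 597 symbols with both called, 196 were higher and 353 lower in both (334 and 192 under total-count scaling) and 48 lie in the quadrants of opposite direction, among them six3, esrra, vrk1 and slc12a3.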

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

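The tests with total-count scaling, lowess offsets, thinned libraries and divided counts, and the splits of the samples, were chosen after the results were seen. Of 140 alternative values for the counts of calls and shares, 132 stayed within 1.5 times the main value or its interval. For calls this compares totals only, so that a split that turned, as under total-count scaling, still counts as unchanged. The 140 also hold the values without the low-count filter, which equal the main ones by construction. The count of pairs with different ratios rose from 342 to 645 with DESeq2 and was 544 (of 1751 tested) with counts divided by 41.1, where the same-sign share was 87.7% and 62 named genes stayed called, as fewer passed the filter. The calls of at least 2-fold fell from 2102 to 822 with glmTreat, which tests whether a change exceeds 2-fold, where the 2102 have only a fitted change of that size. They were 771 at a log2 fold change of at least 2, which is fewer by construction. Leaving out 1 library gave 2457 to 2854 calls in v9.1 (2365 or more of the 3040 kept, 0 reversed), 1788 to 2092 of at least 2-fold, 1823 to 2151 and 1354 to 1604 in v7.1, 907 to 1063 shared symbols, 9 lists in each case, 83 to 92 named genes, a same-sign share of 93.0 to 93.8% and 168 to 285 pairs. With lowess offsets the adhesion and stress lists turned direction (adjusted p 0.903 and 0.886), as did sox17a (0.29 and 0.072) and birc2 (0.25), and 46 of the 3040 calls, while 2048 were kept. The causes of these changes and of that with DESeq2 were not tested. Of 1826 values for named genes and lists, 94 lost their call, 1 gained one and these 5 turned.

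Same-numbered libraries did not deviate together, with correlations of 0.01, 0.00 and -0.01, so the numbers were not taken as pairs. With a replicate block 2869 gene models were called (2761 of the 3040 kept), 2197 in v7.1, 9 lists passed, 8 named gene models lost their call (klf4, sfrp2, tdrd12, casp10, mmp2, ndufb2, gata4 Xelaev18028230m and rps13 Xelaev18021697m, at adjusted p 0.0507 to 0.0981) and the same-sign share was 92.4%. A pseudocount was not needed for counts and was not run, lowess offsets and the block do not apply to the pair test, and leaving out the filter changed nothing since it had removed nothing.

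The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. In each case 1 split, the real one, gave the highest value, 3040 and 2102 calls in v9.1, 2281 and 1615 in v7.1, 1122 shared symbols and 342 pairs, where the highest of the other splits was 0 for each. Every other split put both cell types on each side, which widens the spread within a side, so these zeros say nothing about chance. For lists the real split passed 9, and each of the other splits passed between 3 and 7.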

Other observations

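All tests in this part were chosen after the results were seen. Homeobox and paired box genes, which pattern body axes, were read in PGC libraries in a broader set than the lists hold. Of 152 gene models of 95 such symbols, 49 were higher in PGCs, 18 lower and 85 not called, so that 32.2% were higher against 12.3% of the other 10212 gene models (Fisher's exact test, odds ratio 3.40, 2.36 to 4.85, p 1.43e-10). The odds ratio was 2.37 with total-count scaling and 2.32 with lowess offsets. Fisher's test takes gene models as independent, which those of 1 symbol are not, so its p may be too small. Random sets matched on mean expression gave 15.2 on average and at most 29 in 10000 draws. Leaving out 1 library gave 34 to 57 called higher. On 0 endoderm counts each, hmx3 (Xelaev18034543m) stood at 9.88 ± 2.76, hoxc12 (Xelaev18013572m) at 9.18 ± 5.97 and en2 (Xelaev18032828m) at 6.36 ± 3.56 CPM in PGCs (SD, n = 3), while onecut2 (Xelaev18011063m) fell by 3.01 ± 0.34. These were named after their values were seen. With an estimated correlation camera gave p 0.0462, and 0.00207 with the preset one.

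For this pattern, a scaling trend with expression level is argued against as the whole cause, since 36 of the 49 calls held with lowess offsets. A background equal for all gene models would lift others of the same endoderm level alike. Random sets of other gene models matched on that level gave 29.7 called higher on average and at most 47 in 10000 draws. That argues against an equal background as the whole cause but leaves it open for the larger part, since entry into the tables needed 150 counts and gene models under 1 CPM in endoderm were often called higher whether in the set (27 of 37) or not (97 of 222). Those under 1 CPM were matched as 1 group. Genomic DNA reads need not be equal over gene models, and gene lengths were not used, so genomic DNA stays open. Cells of mesoderm or ectoderm among the PGCs stay open, since the level that a share of such cells would give was not measured: of 88 marker gene models of those layers 31 were higher and 17 lower, and 25 of the 88 are also in the homeobox set. Low-level transcription in PGCs is a candidate explanation that was not tested.

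Germ line RNAs were read in endoderm libraries. Over 8 gene models above 1000 CPM in PGCs and at least 5 in log2 fold change, the endoderm level was 0.315% of the PGC level for grip2, 0.496% for dazl, 0.536% for ddx25, 0.964% for tex15, 1.84% for dnd1 and 2.15% for trank1, a gene named after its values were seen. PGC RNA carried into endoderm libraries as the only source would give 1 ratio, and the ratios differed by far more than their errors (Q per degree of freedom 66.5; Q 466, where 10000 simulations of 1 ratio reached 28.5). Carried RNA up to the lowest level, 0.315% for the grip2 gene model Xelaev18025874m, may still be a part of the source. The lowest levels over the 8 gene models in single libraries were 0.363, 0.187 and 0.285% in endoderm replicates 1, 2 and 3, and endoderm transcription or maternal remnants were not tested.

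The index of dispersion between libraries of a group, the variance over the mean count, had a median of 40.7 in endoderm and 41.5 in PGCs at mean counts of 50 to 6400. Within that range its mean rose from 46.7 to 77.4 in endoderm and from 48.1 to 71.0 in PGCs between the lowest and highest mean counts, and the endoderm median reached 54.4 between 3200 and 6400. Above 6400 the medians were 71.4 and 52.1, so both tests speak for means of up to 6400 only. A constant coefficient of variation between samples would give a slope near 1 on log scales, and 1 minus the slope was at least 0.920 by its 95% bound, which argues against it. Reads copied from few molecules per library would give a slope near 0, and the upper 95% bound was 0.0796. That is close to what copied reads would give, though the rise itself is not given by them. The share of the spread that came from copied reads was not measured. In endoderm replicate 2, 303 gene models had 0 counts although the other endoderm libraries averaged at least 50, with 4 and 194 in endoderm replicates 1 and 3 and 69, 65 and 97 in PGC replicates 1, 2 and 3.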
